A study of Oryza sativa Japonica Group with 27 samples.

How the data were processed

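Structure-seq2 libraries from rice shoots were sequenced on a MiSeq by the authors, per the labels. RNA was extracted, poly(A)-selected, reverse transcribed, ligated and amplified, per the labels' protocols, with the changes of step that name each kind of library. The values used are whole-number counts per transcript, deposited by the authors in 1 table for the standard sequencing primer and 1 for the custom primer, and the file headers name each library by its letter. The submitters' processing notes name cutadapt and Bowtie2, without versions. The genome or transcript build, the annotation, the counting rule and the treatment of reads that match several transcripts are not given in the sources used here. The tables hold no stops per nucleotide, so DMS reactivity was not analysed here.

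The 27 samples are 14 libraries, grouped from the labels into 10 kinds, and a letter read with both primers was treated as 1 library. The standard-primer table served as the main table because it holds all 14 libraries, and the custom-primer table, which holds 13, as a second reading of the same libraries. There were 0 columns of samples outside the labels. Total counts per library ran from 29777 to 410068 with the standard primer and from 27118 to 468337 with the custom primer, so 1 count was worth 2.78 to 26.5 CPM in the former, after scaling by TMM factors. Totals this low limit the precision of single transcripts, and counting limits do not cover PCR duplication.

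Transcripts with at least 10 counts in at least 2 of the libraries fitted were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3 with limma 3.58.1. Comparisons of DMS within a protocol, their difference and the single libraries used 1 fit of all 14 libraries with a mean per kind, which leaves 4 residual degrees of freedom. DMS in both protocols and biotin variation against standard protocol used the 8 replicated libraries with 2 terms. The primers were compared over 13 libraries with library as a block. CPM values were scaled by TMM factors, standard errors were taken as the log2 change divided by the square root of the F statistic, and a transcript with no count in a whole group was given a fold bound from 3 counts over that group. The rule for naming transcripts, fixed before the data were examined, took those past the threshold with a mean of at least 20 counts in a group and no overlap between groups (for the primer, the same sign in at least 12 of 13 libraries), 1 per locus, by the size of the log2 change. Where no table names the genes the rule allows at most 2 in each direction. The condition of no overlap was not applied to the difference of the DMS effect, which has no pair of groups.

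Library composition was compared with two-sided exact permutation tests (the smaller tail doubled) over the 70 divisions of 8 libraries, after thinning to 27118 counts by formula, or to 13423 counts for loci listed with 1 transcript. The counting was checked on loci with 2 transcripts, at least 300 counts and a share of 0.3 to 0.7 for a transcript, and on transcripts with at least 50 counts. The counts of each of the 239 transcripts counted more with the standard primer were compared across libraries with those of every transcript of another locus, beside 5 other transcripts matched on count for each. A list of transcripts was set beside 10000 random lists matched on mean expression over the libraries fitted. The random lists took transcripts singly and do not keep counts that go together, so a share of 0% is not a measure of chance.

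The scripts were tested on simulated counts drawn for the real transcripts, with 200 changed. For DMS in the standard protocol, 28% of transcripts changed 4-fold and 61% of those changed 8-fold were recovered with 4 false calls among 7636 transcripts. For DMS in both protocols the shares were 34% and 63% with 5 false calls among 6166, for Ex Taq 10% and 35% with 2 false calls among 7636, and for the primer 77% and 85% with 8 false calls among 10245. With nothing changed there were 0 calls for DMS in the standard protocol, the comparison in which this was tried. The simulated transcripts were drawn independently from a profile shared by all libraries, while real counts of some transcripts went together. These numbers of false calls may therefore be lower than those in the real data.

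Alternatives fixed before the data were examined were RLE size factors, library totals alone, no filter, a minimum of 50 counts, DESeq2 1.42.0, the custom-primer readings, the sum of both readings, the replicate number as a block, fits of the 8 replicated libraries and leaving out each library in turn. Added afterwards were 1 transcript per locus, leaving out the 239 transcripts counted more with the standard primer, and only loci listed with 1 transcript. Lists of genes by function, shares of ribosomal and organelle RNA, and trends with GC content or length were planned and not run, because 1 of 35679 loci matched a name in the reference table and no sequence was used here.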

Results

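Structure-seq2 reads RNA structure in living tissue with dimethyl sulfate (DMS), a small reagent that methylates unpaired adenine and cytosine, so that reverse transcription stops at the modified base and each sequenced cDNA end marks a stop. The series held 14 libraries from poly(A)-selected RNA of 14-day-old shoots of the rice cultivar Nipponbare, and the labels name 10 kinds of library. The standard protocol had 2 libraries without DMS and 2 with it. The biotin variation, in which biotin was added and cDNA was purified on streptavidin in place of polyacrylamide gels (PAGE), also had 2 libraries without DMS and 2 with it. The other 6 kinds had 1 library each, all without DMS, and each differed from the standard protocol at a named step. They were biotin only (biotin with PAGE purification), Ex Taq (another PCR enzyme), Circligase (another ligase), low RT denaturation (65 °C without salt, where the others used 90 °C with salt), low RT reaction (reverse transcription at 50 °C, where the others used 55 °C) and agarose (final purification on agarose). Each library was read with the standard sequencing primer, and 13 of them, all but Circligase, were also read with a custom primer, which gives 27 samples. The tables held whole-number counts for 42132 transcripts of 35679 loci. They carry transcript identifiers without names, and the files do not pair them with gene symbols, so transcripts are given by identifier, at most 2 in each direction for each comparison. No label says that replicates came from separate plants, so p-values measure the spread between these libraries, which can be technical.

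Total counts with the standard primer were 124680 and 275482 in the standard libraries without DMS, 174728 and 410068 in those with DMS, 29777 and 135804 in the biotin variation without DMS, and 230303 and 155923 in the biotin variation with DMS. The libraries without replicates had 280509 (biotin only), 285714 (Ex Taq), 164907 (Circligase), 230147 (low RT denaturation), 218361 (low RT reaction) and 50816 counts (agarose). With the custom primer the totals ran from 27118 in the biotin variation without DMS, replicate 1, to 468337 in the standard protocol with DMS, replicate 2. At these depths 1 count was worth 2.78 CPM (counts per library total scaled by TMM factors, as in all CPM values here) in the deepest standard-primer library and 26.5 CPM in the shallowest, and a count of 0 allowed up to 8.33 CPM and 79.6 CPM (3 counts). These limits cover counting error only, since the reads carry no molecular identifiers in the sources used here.

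Fewer transcripts were detected in the biotin variation than in the standard protocol at the same depth. Thinned to 27118 counts, the 4 biotin variation libraries showed 7176 ± 1340 transcripts (SD, n = 4) and the 4 standard libraries 8972 ± 88.3 (SD, n = 4), a difference of -1796 (two-sided exact permutation test, p = 0.0286, the smallest p that 4 against 4 libraries allow). In the custom-primer readings the difference was -2889 (6078 ± 1870 against 8967 ± 116, SD, n = 4 each; exact permutation p = 0.0286). On loci listed with 1 transcript, thinned to a lower depth of 13423 counts, it was -703.2 (4267 ± 778 against 4970 ± 71.7; exact permutation p = 0.0571). The 10 most abundant transcripts took 13.9% ± 5.07 of the counts in the biotin variation and 7.86% ± 0.259 in the standard protocol (SD, n = 4 each; exact permutation p = 0.0286). Libraries with DMS showed 8462 ± 692 transcripts and those without 7685 ± 1750 (SD, n = 4 each; exact permutation p = 0.543), and the 10 most abundant transcripts took 9.98% ± 2.68 and 11.8% ± 6.40 (exact permutation p = 0.8). These permutations did not keep libraries within their protocol, so the protocol difference adds to the spread. With and without DMS the standard libraries showed 9036 and 8952 against 9044 and 8855 transcripts. In the biotin variation the libraries showed 7542 and 8320 against 5237 and 7604. Of the single libraries, Circligase showed 7723 transcripts at this depth and the other 5 between 8620 and 9191. Without the shallowest library, the biotin variation without DMS replicate 1, the DMS differences turned to -38.5 transcripts and 1.32 percentage points, and the protocol differences were -1150 transcripts and 3.65 percentage points.

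**Figure D1:**
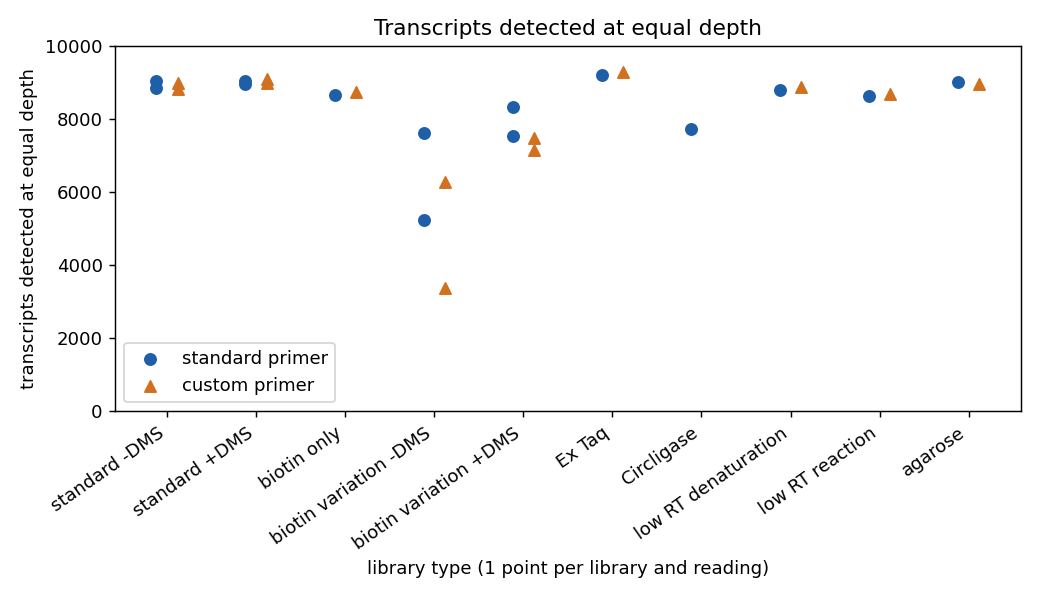
Transcripts detected after thinning each library to 27118 counts (y axis, number of transcripts) for each kind of library (x axis), with 1 point per library, circles for the standard primer and triangles for the custom primer. The biotin variation lies below the standard protocol with both primers, at 5237 to 8320 transcripts with the standard primer against 8855 to 9044.

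Agreement between libraries was measured as Pearson's r across transcripts of log2(CPM + 1), and transcripts are not independent replicates. Replicates read with the standard primer gave r = 0.731 and 0.754 in the standard protocol without and with DMS, and r = 0.424 and 0.73 in the biotin variation without and with DMS. With the custom primer these were 0.797 and 0.856 in the standard protocol, and 0.386 and 0.7 in the biotin variation. The same library read with both primers gave a mean r of 0.763 ± 0.0929 (SD, n = 13), from 0.516 in the agarose library to 0.849 in the standard protocol with DMS, replicate 2. Each library was counted as 1 replicate. The chi-square per degree of freedom between replicates, with reads taken as independent, ran from 1.35 to 11.2 over the replicated groups and both primers. In the standard protocol without and with DMS it was 3.03 and 2.82 with the standard primer and 1.35 and 1.64 with the custom primer. In the biotin variation without and with DMS it was 7.68 and 3.59 with the standard primer and 11.2 and 2.97 with the custom primer.

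In this method the -DMS libraries give the background of stops that do not come from the reagent, and here the total count per transcript was compared between +DMS and -DMS libraries. In the standard protocol 67 of 7636 transcripts tested passed an adjusted p of 0.05, and 63 of them, from 52 loci, were lower with DMS while 4 were higher. OS03T0307300-01 fell from 191.8 ± 5.65 to 4.17 ± 5.89 CPM (SD, n = 2 each), a log2 change of -4.92 (SE 0.943, edgeR adjusted p = 0.0127). OS05T0586600-01 fell from 168.5 ± 14.6 to 11.3 ± 12.1 CPM (log2 change -4.20, SE 0.879, edgeR adjusted p = 0.0263). OS02T0530100-02 rose from 43.3 ± 47.2 to 387.3 ± 33.3 CPM (log2 change 2.93, SE 0.692, edgeR adjusted p = 0.0454), and OS02T0101500-02 rose from 627.2 ± 76.2 to 2605 ± 176 CPM (log2 change 2.05, SE 0.385, edgeR adjusted p = 0.0109). All 4 went the same way in the custom-primer readings, with log2 changes of -6.12, -4.17, 3.05 and 2.00, and 61 of the 67 transcripts were called there with the same sign. Under the alternatives in which it was tested OS02T0530100-02 did not pass the threshold in 9 of 15 (highest adjusted p 0.428), OS05T0586600-01 in 6 of 13 (0.505), OS02T0101500-02 in 4 of 15 (0.172) and OS03T0307300-01 in 2 of 13 (0.132). The custom-primer readings are further reads of the same libraries and not more replicates.

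By their median, the 63 transcripts lower with DMS were also low in all 4 biotin variation libraries, with and without DMS. Against the 6 single-library protocols, 56 of the 63 had a log2 change below 0 in the biotin variation without DMS, 47 of them called lower, and all 63 did in the biotin variation with DMS, 52 of them called lower. Against the mean of the single-library protocols, their median log2 CPM was -2.24 and -2.58 in the standard libraries with DMS, -2.96 and -2.42 in the biotin variation without DMS, and -2.24 and -2.47 in the biotin variation with DMS. It was 0.152 and 0.105 in the standard libraries without DMS and lay between -0.482 and 0.464 in the single-library protocols, biotin only included at -0.414. Set against the 5 other single-library protocols, biotin only had a median of -0.419 with 53 of the 63 below 0 and none called, and 0% of 10000 random lists matched on mean expression lay as low. The random lists took transcripts singly, while the 63 were chosen for a shared change. A shift of the whole set in 1 library can thus give 0%, and no conclusion on biotin is drawn from it. Ex Taq, a library without biotin, was the lowest of the single-library protocols at -0.482 and was not set against random lists. The number of calls in the standard protocol rested on single libraries, with 27 without the -DMS replicate 2, 34 without the +DMS replicate 1 and 7 without the +DMS replicate 2. The share of higher calls, 5.97%, was 16.3% with RLE size factors and 22.5% with library totals alone.

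**Figure D2:**
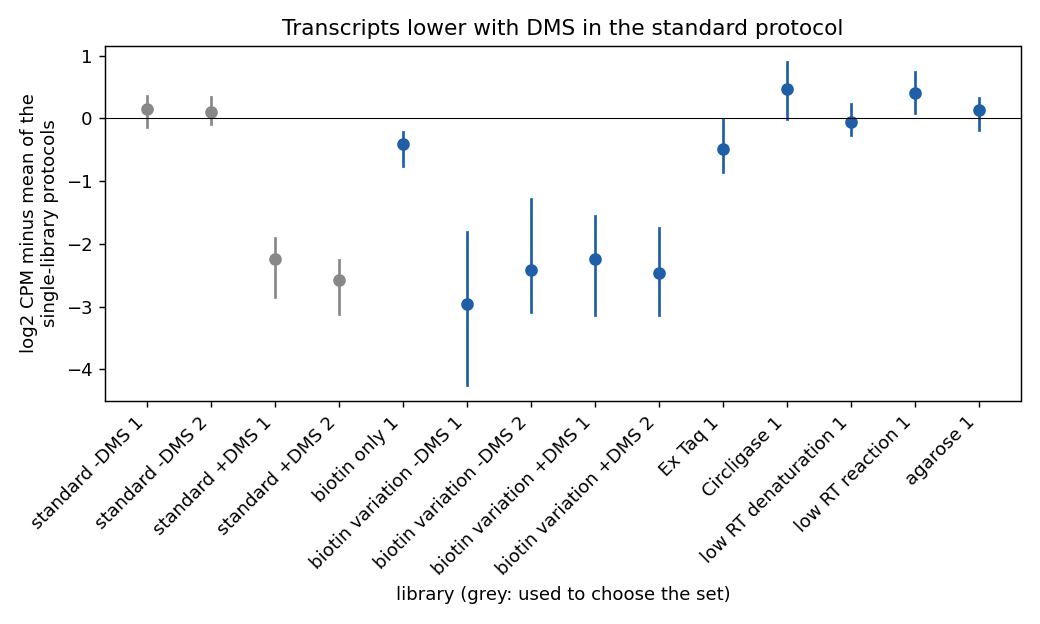
Median over the 63 transcripts lower with DMS in the standard protocol of log2 CPM minus the mean of the single-library protocols (y axis, log2 units), for each standard-primer library (x axis), with lines from the lower to the upper quartile over transcripts. The libraries used to choose the transcripts are grey. The 4 biotin variation libraries lie at -2.96 to -2.24, near the standard libraries with DMS.

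In the biotin variation 79 of 7636 transcripts passed the same threshold for DMS, 28 higher and 51 lower, from 64 loci. OS01T0933200-00 was at 238.6 ± 76.9 CPM with DMS and 4.21 ± 5.95 without (SD, n = 2 each; log2 change 5.08, SE 1.01, edgeR adjusted p = 0.0253). OS01T0101200-01 was at 222.8 ± 89.2 and 4.21 ± 5.95 CPM (log2 change 5.00, SE 1.03, edgeR adjusted p = 0.0277). For each of these 2 transcripts the -DMS libraries held 1 count. OS11T0581700-01 and OS10T0422500-01 had no count in either +DMS library and 585.4 ± 185.6 and 520.4 ± 165 CPM without DMS, which makes them at least 52.7-fold and 46.8-fold lower (floor of 3 counts over the group; edgeR adjusted p = 0.0117 for each), or 22-fold and 19.5-fold without the +DMS replicate 1. Their counts went together, at 236 and 207 in the standard libraries without DMS, 239 and 210 in those with it and 81 and 72 in the biotin variation without DMS, so they cannot be taken as independent. Both belong to a set of 239 transcripts counted far more in the standard-primer table than in the custom-primer table, as did 40 of the 79 called. Neither was tested in the custom-primer readings, where neither had a count in the biotin variation, with or without DMS. The second reading of the same libraries thus did not show the level from which they fell. The 4 named here did not pass the threshold in 4 of 14 (OS01T0101200-01), 5 of 15 (OS01T0933200-00) and 5 of 13 alternatives (the others), with a highest adjusted p of 0.279. Of the 79, 42 were tested in both readings, and 18 of these were called in both with the same sign, 14 higher and 4 lower. The median log2 change of all tested transcripts was 0.648, and it was 0.336 with RLE size factors and 0.172 with library totals alone, with 20.8% and 10.2% of calls higher in place of 35.4%. Without the 239 transcripts there were 167 calls, 128 of them higher, so the direction of most calls depended on that set. The number of calls was 9 without the -DMS replicate 1, 451 without the -DMS replicate 2, and 0 without either +DMS library.

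The DMS effect differed between the protocols for 18 transcripts of 11 loci, all with a higher log2 change in the biotin variation. OS08T0468700-00 changed by -4.19 (SE 0.638, edgeR adjusted p = 0.00188) in the standard protocol and by 5.52 (SE 2.05, edgeR adjusted p = 0.147) in the biotin variation, a difference of 9.71 (SE 1.81, edgeR adjusted p = 0.0228). OS08T0468100-01 changed by -4.06 (SE 0.612, edgeR adjusted p = 0.00181) and 5.35 (SE 2.06, edgeR adjusted p = 0.159), a difference of 9.41 (SE 1.81, edgeR adjusted p = 0.0251). Neither had a count in the biotin variation without DMS, so the fitted sizes depend on the prior count. Their counts went together, at 159 and 171 in the standard libraries without DMS, so they cannot be taken as independent. They did not pass the threshold in 8 and 9 of 18 alternatives (highest adjusted p 0.359), and of the 18 transcripts 10 were called in both readings with the same sign. The median difference of all tested transcripts was 0.676 with TMM factors, 0.387 with RLE size factors and 0.152 with library totals alone, so the whole distribution was shifted in the direction of the calls. No transcript called was lower in the difference with TMM or RLE factors, and 2 of 17 were with library totals alone. The number of calls was 0 without either biotin variation +DMS library, 4 without the standard +DMS replicate 2, 33 without the biotin variation -DMS replicate 1, 54 without the standard +DMS replicate 1, 109 without the standard -DMS replicate 1 and 167 without the biotin variation -DMS replicate 2.

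With both protocols in 1 fit, 13 transcripts were higher and 21 lower with DMS among 6166 tested, from 27 loci. OS01T0102300-01 was at 294 ± 68.1 CPM with DMS and 31.3 ± 28.6 without (SD, n = 4 each; log2 change 2.80, SE 0.534, edgeR adjusted p = 0.0218). OS06T0708832-00 was at 583.2 ± 350.3 and 88.7 ± 72.1 CPM (log2 change 2.20, SE 0.474, edgeR adjusted p = 0.0377). OS03T0152000-01 was at 35.9 ± 16.5 CPM with DMS and 368.9 ± 172.8 without (log2 change -3.53, SE 0.495, edgeR adjusted p = 0.00136), and OS01T0606900-01 at 20.9 ± 10.2 and 206.5 ± 74.6 CPM (log2 change -3.41, SE 0.558, edgeR adjusted p = 0.00706). In the custom-primer readings 31 of the 34 were called with the same sign. Of 18 alternatives, OS01T0102300-01 did not pass the threshold in 3 (highest adjusted p 0.181), OS06T0708832-00 in 6 (0.202) and OS03T0152000-01 in 1 (0.0533), and OS01T0606900-01 did not in 2 of 17 (0.102). The number of calls was 8 and 133 without the standard -DMS replicate 1 and 2, 21 and 148 without the standard +DMS replicate 1 and 2, 142 without the biotin variation -DMS replicate 1, and 0 and 3 without the biotin variation +DMS replicate 1 and 2.

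Between the protocols, with DMS treatment as a covariate, 306 transcripts were higher and 282 lower in the biotin variation among 6166 tested, from 495 loci. OS12T0291200-00 was at 314.2 ± 164.1 CPM in the biotin variation and 26.9 ± 31.9 in the standard protocol (SD, n = 4 each; log2 change 3.69, SE 0.611, edgeR adjusted p = 0.0046). OS09T0299400-00 was at 206.3 ± 136.7 and 19.1 ± 11.9 CPM (log2 change 3.47, SE 0.708, edgeR adjusted p = 0.0118). OS08T0543275-00 had no count in the 4 biotin variation libraries and 1152 ± 1371 CPM in the standard libraries, where it had 65 and 2 counts without DMS and 475 and 294 with it, which makes it at least 164-fold lower, or 69.6-fold without the standard +DMS replicate 1 (floor of 3 counts over the group; edgeR adjusted p = 0.00365). With the custom primer it had 38.9 and 132.3 CPM in the standard protocol without and with DMS, and no count in the biotin variation. OS01T0655800-01 was at 2.22 ± 4.44 and 128.8 ± 38.1 CPM (log2 change -5.25, SE 0.934, edgeR adjusted p = 0.00553). The first 3 belong to the 239 transcripts counted more in the standard-primer table. OS12T0291200-00 had no count in any custom-primer reading and OS09T0299400-00 at most 4 counts in each, and neither was tested there. The share of higher calls was 52% with TMM factors, 33.2% with RLE size factors and 36% with library totals alone, and the median log2 change of all tested transcripts was -0.18, -0.387 and -0.349. In the custom-primer readings 268 were higher and 669 lower, and 282 transcripts were called with the same sign in both readings. The number of calls was 195 and 238 without the standard -DMS replicate 1 and 2, 332 and 245 without the standard +DMS replicate 1 and 2, 1186 and 80 without the biotin variation -DMS replicate 1 and 2, and 143 without the biotin variation +DMS replicate 2.

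The biotin variation without DMS was also set against the biotin only library, which carried biotin but was purified by PAGE. Of 7636 transcripts, 5 were higher and 107 lower in the biotin variation, from 87 loci. This fit, like those for the other single libraries, pools the spread over the 4 replicated groups and assumes that the lone library varies like them. OS04T0113800-01 was at 624.6 ± 205.3 CPM (SD, n = 2) in the biotin variation and 16.9 CPM in the biotin only library (log2 change 5.12, SE 1.03, edgeR adjusted p = 0.0187). OS08T0543275-00 and OS05T0463600-01 had no count in the biotin variation and 204 and 106 counts in the biotin only library, at least 44.9-fold and 23.3-fold lower (floor of 3 counts over the group; edgeR adjusted p = 0.0397 and 0.0266). Without the biotin variation -DMS replicate 2 the bounds were 10.8-fold and 5.61-fold. The call for OS08T0543275-00, 1 of the 239 transcripts above, did not pass the threshold in 8 of 10 alternatives (highest adjusted p 0.283), and the biotin only library held 55.4 CPM of it with the custom primer (adjusted p 0.0884) against 860.1 with the standard primer. The call for OS05T0463600-01 did not pass in 3 of 11 (highest adjusted p 0.18). In the custom-primer readings 15 were higher and 282 lower. The median log2 change of all tested transcripts was -0.667, and -0.437 with library totals alone, where 16.7% of calls were higher in place of 4.46%. Without the biotin variation -DMS replicate 1 the number of calls was 509.

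The 6 single-library changes of protocol were each set against the 2 standard libraries without DMS. With TMM factors and all libraries, Circligase was the only change with calls by edgeR, with 14 transcripts higher and 4 lower, from 17 loci. OS06T0151850-00 was at 8588 CPM with Circligase and 750.6 ± 182.6 CPM (SD, n = 2) in the standard protocol (log2 change 3.52, SE 0.525, edgeR adjusted p = 0.00382), and OS01T0666101-00 at 8580 and 750.6 ± 182.6 CPM. These had 1021 and 1020 counts with Circligase and 235 counts each in the standard libraries, so their counts cannot be taken as independent. OS06T0151850-00 was also above the standard libraries in Ex Taq (3655 CPM), low RT denaturation (2929 CPM), biotin only (1543 CPM) and low RT reaction (1394 CPM), and at 513.8 CPM in agarose. OS06T0693200-02 was at 8.41 CPM with Circligase and 1298 ± 18.4 CPM in the standard protocol (log2 change -7.15, SE 1.26, edgeR adjusted p = 0.0114), and all other single libraries were also below the standard protocol, at 72.2 (low RT denaturation), 97.9 (low RT reaction), 103.7 (Ex Taq), 362.6 (biotin only) and 599.4 CPM (agarose). OS08T0188151-00 had no count with Circligase and 108 counts in the standard libraries, at least 13.3-fold lower (floor of 3 counts; edgeR adjusted p = 0.0184). All other single libraries were below its standard level of 336.8 ± 54.9 CPM too. They held 63.84 (Ex Taq), 67.05 (low RT denaturation), 149.8 (low RT reaction), 235.5 (agarose) and 236.1 CPM (biotin only). Without the -DMS replicate 1 there were 8 calls, and 43 without the -DMS replicate 2.

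In the same fit no transcript passed an edgeR adjusted p of 0.05 for biotin only, Ex Taq, low RT denaturation, low RT reaction or agarose. Transcripts with an unadjusted p under 0.05 numbered 226, 232, 273, 159 and 94 of 7636, and DESeq2 called 1, 13, 32, 10 and 0. Each count with an unadjusted p under 0.05 was below the share of 0.05 that unchanged transcripts would give, so small p-values were not in excess. On simulated data a single library set against the pair recovered 10% of transcripts changed 4-fold and 35% of those changed 8-fold, in the Ex Taq comparison, so most changes of these sizes would not have been detected at this depth. Without the -DMS replicate 1 the counts were 5, 16, 14, 5 and 4, and without the -DMS replicate 2 they were 0, 0, 51, 3 and 0.

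The sequencing primers were compared within the 13 libraries read with both, with library as a block, so the test concerns the reading and the counting and not the plants. Of 10245 transcripts, 2628 were higher and 2625 lower with the custom primer. Loci listed with 1 transcript had 2418 transcripts higher and 543 lower of 5522 tested, with a median log2 change of 0.499, and loci with several transcripts had 210 higher and 2082 lower of 4723, with a median of -0.413. When loci with several transcripts were left out before scaling, 249 were higher and 731 lower, so the direction for loci with 1 transcript depended on the transcripts that set the scale. OS11T0130200-01 was at 94.2 ± 49.3 CPM with the custom primer and 43.6 ± 26.3 with the standard primer (SD, n = 13 each; log2 change 1.12, SE 0.176, edgeR adjusted p = 3.36e-07), and OS02T0635000-01 at 108.7 ± 72.4 and 52.9 ± 46.9 CPM (log2 change 1.11, SE 0.191, edgeR adjusted p = 2.17e-06). OS07T0669500-01 had no count with the custom primer and 330 counts with the standard primer, at least 149-fold lower (floor of 3 counts over the 13 readings; edgeR adjusted p = 1.33e-22). OS03T0441400-02 was at 1.26 ± 2.60 and 241.7 ± 190 CPM (log2 change -6.57, SE 0.282, edgeR adjusted p = 1.91e-28). Of 9393 transcripts with at least 100 counts over both readings, 239 had a share of counts more than 4 times higher with the standard primer and 0 the reverse. They took 2.81% of the standard-primer counts and 0.311% of the custom-primer counts.

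Counts of transcripts of the same locus moved together in the standard-primer table. At 409 loci with 2 transcripts, the split of counts between them varied across the 13 libraries with a median ratio of 0.196 to the variance of independent reads, where 1 is a random split. In the custom-primer table the median ratio was 1.36 over 309 loci, and simulated random splits gave 0.95. Of 8778 transcripts with at least 50 standard-primer counts, 202 had the same count as another transcript in every library, 78 of them as a transcript of another locus. Of 9801 such transcripts in the custom-primer table, 0 did.

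**Figure D3:**
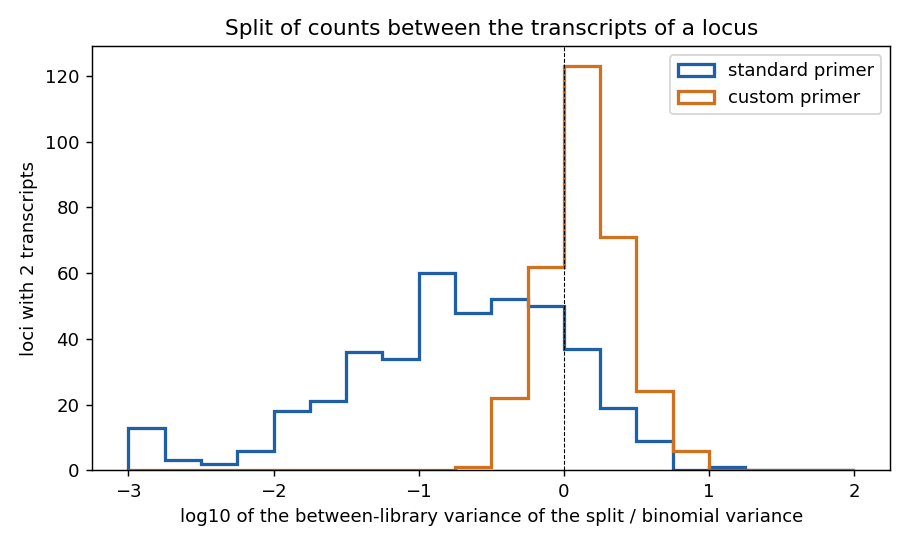
Loci with 2 transcripts (y axis, number of loci) by the log10 ratio of the between-library variance of the split of counts to the binomial variance (x axis), for the standard-primer and custom-primer tables, with the dashed line at a random split and the lowest ratios drawn at the left end. The standard-primer loci have a median ratio of 0.196 and the custom-primer loci of 1.36.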

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

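The correlation across libraries below was planned before its value was seen. The tests of depth and of DMS treatment were chosen only after their results were seen.

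The DMS effect differed between the standard protocol and the biotin variation, by a test of the difference itself, for 18 transcripts, and OS08T0468700-00 and OS08T0468100-01 had the largest differences among those that met the naming rule, 9.71 and 9.41 on the log2 scale, with counts that went together over the libraries (159 and 171 in the standard libraries without DMS), so they are not independent cases. In OS08T0468700-00 the standard protocol held 487.6 ± 51.4 CPM without DMS and 30.1 ± 22.9 with it (SD, n = 2 each), and the biotin variation held no count without DMS and 36.2 ± 24.2 CPM with it. OS08T0468100-01 held 521.6 ± 45.3, 34.8 ± 25.6, no count and 31.7 ± 17.9 CPM. A rise with DMS in the biotin variation is not shown, since the fold bounds of 1.89 and 1.66 (floor of 3 counts over the group) fell to 0.454 and 0.398 without the -DMS replicate 2, and both transcripts stood in the treated libraries at levels like those of the standard libraries with DMS. Among other alternatives, neither call held in the sum of both readings, with the replicate number as a block or without either biotin variation +DMS library, and OS08T0468100-01 did not pass in the custom-primer readings (adjusted p 0.0673).

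Both belong to a wider pattern: by their median, the 63 transcripts lower with DMS in the standard protocol were also low in the biotin variation without DMS, at a log2 difference of -2.60 (SD over transcripts 2.53; 56 of the 63 below 0 and 47 called lower) from the 6 single-library protocols, which share no library with the comparison that picked them, and 0% of 10000 matched random lists lay as low. The random lists took transcripts singly, so their 0% does not allow for counts that go together. The median of all tested transcripts was -0.504, and with the 9 transcripts that had no count in that group set to 3 counts the median of the set was -2.53. Low depth of 1 library is argued against, since without the biotin variation -DMS replicate 1 the median was -2.66. DMS treatment, the biological explanation, is argued against as the cause of the low level in the biotin variation without DMS. Those libraries, never treated, lay at -2.96 and -2.42 where the single-library protocols lay between -0.482 and 0.464. This follows from the design and does not test whether DMS lowered the set in the standard protocol, which stays open. An added effect of DMS within the biotin variation stays open too. The set moved there by a median of 0.237 against 0.648 for all tested transcripts, with 26 of the 63 below 0, 3 called lower and 0 higher, and 0% of 10000 matched random lists lay as low. Those lists were matched on mean expression over all libraries, not on the low level of the set in the biotin variation. They therefore cannot decide whether DMS had an added effect there. RNA preparations that differed between libraries stay open, because the labels name no preparation. The standard DMS contrast and the contrast of the biotin variation without DMS against the single-library protocols, which share no library, correlated with r = 0.204 across 7636 transcripts. The biotin variation protocol and biotin itself also stay open. Biotin only was lower than all matched lists though by less (median -0.419 against the 5 other single-library protocols). That low value was not particular to biotin: against the other single-library protocols Ex Taq, a library without biotin, lay at -0.482 and biotin only at -0.414. Ex Taq was not set against matched lists. The place of biotin only below those lists does not decide whether biotin lowered the set, since they took transcripts singly.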

How the results depend on the processing

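Alternatives using 1 transcript per locus, leaving out the transcripts in excess in the standard-primer table, or using only loci listed with 1 transcript were chosen after seeing the data. Of 381 values of the 29 named results under an alternative, 301 kept their direction and their side of the threshold, 80 kept the direction without passing it and 0 reversed. Alternatives in which a named transcript was not tested were left out and not counted as failures. In the protocol comparison OS12T0291200-00 and OS09T0299400-00 were thus scored in 15 and 13 alternatives, and OS01T0655800-01 in 17. Each of the 8 comparisons with calls changed its count by more than 1.5 times under some alternative other than leaving out a library, and the cause was not tested except where stated. For DMS in the standard protocol (67 calls) the count was 102 with library totals alone, 43 with no filter on low counts, 147 with at least 50 counts, 107 in the custom-primer readings, 18 in the sum of both readings, 39 with the replicate block, 24 with 1 transcript per locus (fewer transcripts tested), 143 without transcripts in excess and 134 with DESeq2. For DMS in the biotin variation (79) it was 127 with no filter, 3 with at least 50 counts, 0 in the sum of both readings, 52 with only the 8 replicated libraries, 41 with 1 transcript per locus, 167 without transcripts in excess (128 higher) and 132 with DESeq2. For the difference of the DMS effect (18) it was 35 with no filter, 8 with at least 50 counts, 0 in the sum of both readings, 9 with the replicate block, 3 with 1 transcript per locus, 44 without transcripts in excess and 40 with DESeq2. For DMS in both protocols (34) it was 58 with no filter, 79 with at least 50 counts, 105 in the custom-primer readings, 9 with 1 transcript per locus, 147 without transcripts in excess and 248 with DESeq2. For the biotin variation against the standard protocol (588) it was 916 with no filter, 201 with at least 50 counts, 937 in the custom-primer readings, 912 in the sum of both readings, 368 with 1 transcript per locus, 1133 without transcripts in excess and 1139 with DESeq2. For biotin only against the biotin variation without DMS (112) it was 297 in the custom-primer readings, 24 with 1 transcript per locus and 489 without transcripts in excess. For the primer (5253) it was 1410 with at least 50 counts, 3247 with only the 8 replicated libraries, 2885 with 1 transcript per locus and 980 with only loci listed with 1 transcript, and 3629 with no replicate block.

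For Circligase (18 calls) the count was 31 without transcripts in excess and 48 with DESeq2. Against 0 calls by edgeR, biotin only had 2 without transcripts in excess and 1 with DESeq2. Ex Taq had 7 with RLE size factors, 7 with library totals alone, 4 with no filter, 6 without transcripts in excess and 13 with DESeq2. Low RT denaturation had 31 with no filter, 3 without transcripts in excess and 32 with DESeq2, and low RT reaction had 4 without transcripts in excess and 10 with DESeq2. The difference in transcripts detected at equal depth between the protocols was -2889 in the custom-primer readings and -703.2 on loci listed with 1 transcript, at the lower depth of 13423 counts (exact permutation p = 0.0571).

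Leaving out 1 library at a time, calls ran from 7 to 52 for DMS in the standard protocol, from 0 to 451 for DMS in the biotin variation, from 0 to 167 for the difference, from 0 to 148 for DMS in both protocols, from 80 to 1186 for the protocols and from 130 to 509 for biotin only against the biotin variation. For the single libraries they ran from 8 to 43 (Circligase), 0 to 5 (biotin only), 0 to 16 (Ex Taq), 14 to 51 (low RT denaturation), 3 to 5 (low RT reaction) and 0 to 4 (agarose). The difference between the protocols ran from -2177 to -1150 transcripts detected and from 3.65 to 7.25 percentage points in the share of the 10 most abundant. With the smaller tail doubled, each of these gave 0.0571, the smallest that 3 against 4 libraries allow. By the absolute difference, a form chosen after seeing the data, p was 0.0286 for both quantities without any 1 biotin variation library, and 0.0571 (transcripts detected) and 0.0857 (share) without any 1 standard library. The differences with DMS ran from -38.5 to 1230 transcripts and from -3.23 to 1.32 percentage points, and both changed sign without the biotin variation -DMS replicate 1. Where a group is left with 1 library, its spread is assumed to equal that of the other groups.

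Over the 6 pairs of groups, the correlation of the replicate differences was 0.169 between the standard libraries without and with DMS. It ran from -0.0692 to -0.000529 in the other pairs. Pairing by replicate number was thus not seen outside the standard protocol, and small values in shallow libraries do not exclude it. The replicate block moved the protocol comparison to 436 calls and DMS in both protocols to 25, within 1.5 times. The median log2 change of all tested transcripts moved with the scaling by more than 0.1 for the biotin variation comparisons given above and for Circligase (-0.086 with TMM, -0.343 with totals alone), Ex Taq (-0.05, 0.132 with RLE) and agarose (-0.259, -0.075 with RLE). Lists of genes, GC content and length trends and readings per nucleotide were not run, for want of names, sequences and positions.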

Other observations

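Tests of counting noise, abundant transcripts and distinct molecules were chosen only after their results were seen, the test of shared reads after related results were seen, and the splits of the samples were planned before.

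Between the protocols, which share no library in this comparison, the log2 changes with DMS correlated with r = 0.135 across 7636 transcripts (Spearman 0.151), and transcripts are not independent. Of the transcripts called in each, 3 were lower in both and 0 higher in both, where independent lists of these sizes would share 0.421 and 0.0147.

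The 239 transcripts counted far more in the standard-primer table than in the custom-primer table may come in part from reads counted in every transcript they match, which stays open. Of these, 18.4% had counts that followed those of a transcript of another locus more closely than independent reads would (chi-square per degree of freedom under 0.1), against 3.1% of other transcripts matched on count, so the origin of most of them is not shown. Counting noise between the readings is argued against, since 239 transcripts lay more than 4-fold in one direction and 0 in the other. No biological explanation was tested, because both tables read the same libraries.

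In the biotin variation, fewer transcripts were detected at equal depth. A few transcripts taking most of the counts is argued against as the whole cause: without the 100 most abundant transcripts the difference was -1168 transcripts (6361 ± 1010 against 7529 ± 32.8, SD, n = 4 each; exact permutation p = 0.0286, the smallest the design allows). Fewer distinct cDNA molecules in the biotin variation libraries stays open: on loci with 1 transcript, both readings of a library agreed better than replicates did by 0.339 and 0.421 in r without DMS and by 0.128 and 0.018 with DMS in the biotin variation, against -0.117 and 0.0523, and -0.0665 and 0.0437, in the standard protocol. Any difference between replicate libraries gives such a gap, so it does not point to fewer molecules. Streptavidin purification was used in the biotin variation libraries alone. The biotin only library, purified by PAGE, showed 8665 transcripts at equal depth with the standard primer. The biotin variation libraries showed 5237 to 8320 and the standard libraries 8855 to 9044. Since biotin only is 1 library, the step that differs stays open.

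For the biotin variation against the standard protocol, 1 of 34 splits of the 8 libraries, the real one, gave 588 calls, and the highest other gave 28. For the primers, 1 of 30 flips of the readings within libraries, the real one, gave 5253 calls, and the highest other gave 96. Chance in how the libraries fell into groups is argued against in both, but so few splits cannot exclude it. The other splits also mix the kinds compared, which adds to their spread. The flips cannot separate the primer from the counting, whose rule is not given for either reading. For DMS in both protocols chance is not argued against, since 2 of 34 splits gave as many as the real 34 calls, and the highest other gave 61. That split set the replicate 2 libraries of the standard protocol and the +DMS libraries of the biotin variation against the rest, and with the replicate number as a block there were 25 calls.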
